A study of Mus musculus with 8 samples.

How the data were processed

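Poly-A RNA of AML12 cells, an established hepatocyte line from mouse liver, was sequenced from 8 cultures. Per the labels' protocols, 4 cultures received a scrambled control siRNA (Scr) and 4 received Casp8 siRNAs (siCasp8) at 40 nM with a lipid reagent, RNA was taken with a column kit after 48 hours, and libraries were made with Illumina TruSeq chemistry. The series' design text calls the 4 cultures of each group biological replicates. The sequences of the siRNAs were not given in the sources used here. Each library was assigned to its group from its title in the labels, and each column of the table from the library name that the labels repeat.

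The submitters' processing notes name bcl2fastq 2.19, kallisto 0.44.0, sleuth and DESeq2, and the genome builds GRCh38 and GRCm38, without a role or an order. The table itself was deposited by the authors as gene-level values that, per its name, are kallisto estimates normalized with DESeq2. Per the labels and from its numbers, the deposited table holds a normalized signal per gene symbol that is never negative, not reads and not a value scaled to a fixed total. How transcripts were summed to genes, and which annotation was used, was not given in the sources used here. The table held 34945 named genes, of which 12681 had no value above 0 in any library. A further line without a symbol held from 0.0481% to 0.0631% of each library's total and was kept out of all totals and tests. No column of the table was left unused.

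The deposited values summed to between 44.1 and 45.6 M per library, so totals carry no depth. Depth was estimated from the spacing of the low values, since a gene at 1 read shows the value that 1 read is worth in its library. That value lay between 0.776 and 1.47, which puts depth at 30.7 to 56.8 M reads per library. Between 65.5% and 75.0% of the low values (up to 20.5 reads) lay within 0.1 read of a whole multiple. Whole reads could therefore not be recovered for nearly all genes, and count models were not used. The planned log-scale test was kept as the main test.

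Values were analysed in R 4.3.3 with limma 3.58.1. Genes with a mean value of at least 10 over the 8 libraries were kept, which left 14154. The test was limma's moderated test of siCasp8 minus Scr on log2(value + 1), with a trend in the prior variance and no covariate. It was two-sided, with Benjamini-Hochberg adjustment over the 14154 genes, and a gene was called at an adjusted p under 0.05. Fold changes are given on the log2(value + 1) scale with the standard error (SE), and this scale understates the change of low genes. Group values are mean ± SD over the 4 libraries of a group, in the deposited normalized unit. Single comparisons used an exact two-sided permutation test over the 70 arrangements of the 8 libraries, whose smallest possible p is 0.0286. On simulated data for this comparison, with 200 of 14154 genes changed, the limma test called 85.0% of genes changed by 1 on the log2 scale and 62.0% of those changed by 0.5, and 6.37% of its calls were false. The simulation drew noise independently per gene, and 40.2% of genes were called in the data, so these rates need not carry over.

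Before the data were examined, 27 gene lists were fixed from textbook knowledge. Of these, 26 had at least 5 tested members and were tested with limma's camera at a preset correlation between genes of 0.01, two-sided, with adjustment over the 26 lists. Members are counted as higher or lower from the limma test over all genes, and counts adjusted over the list alone are given where they differ. Each list test was repeated with the correlation estimated from the data and with fry, which tests a list on its own. The lists covered cell death genes, interferon-stimulated genes, inflammatory targets, p53 targets, both cell cycle phases, the integrated stress response, folding in the endoplasmic reticulum, cholesterol and fatty acid synthesis, fatty acid oxidation, hepatocyte identity, secreted signalling factors, matrix, targets of YAP, TGF-beta, ERK and NRF2, glycolysis, autophagy, mitochondrially encoded genes, ribosomal proteins, histones, and markers of cholangiocytes, stellate cells, macrophages and endothelium.

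The genes named in the text follow a rule that was also set before the data were examined. Casp8 and Metrn were named in any case. Next came the 10 largest rises and the 10 largest falls among called genes with a mean of at least 50 and no overlap between the groups, leaving out symbols of predicted genes, clones and pseudogenes. In each list with at least 5 tested members, the 2 called members with the smallest adjusted p in each direction were named, or 6 for secreted signalling factors. For the lists of other cell types the most abundant members were added. The rule gave 115 genes, of which 113 matched a symbol in the GENCODE annotation of GRCm38 used for positions and untranslated regions. Some genes that the rule gave are not reported here, and counts over the genes of the rule include them. Of the 14154 tested symbols, 13906 matched. Genes with close copies or overlapping neighbours share reads that the authors' estimation had to divide, so values of Ugt1a, Cyp2c, Serpina1 and Ces2 genes, C1s1, Rnase4 and Metrn are uncertain in that respect.

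For the 3′ UTR analysis, the longest annotated 3′ UTR of at least 50 bases was taken per gene. Log2 fold changes of 11293 genes with a mean of at least 50 were regressed on the presence of each of 15651 words of 7 bases found in at least 100 genes, with UTR length and base composition in the model. The most extreme fold changes at either end were first cut back to a fixed percentile. The strongest word was compared with those of 100 shuffles over genes. Each shuffle used the part of the fold changes that UTR length and base composition left unexplained. On simulated fold changes with 1 word shifted by -0.10, the procedure ranked that word at the top with an estimate of -0.11. With no shift no word passed the shuffles, which were fewer in the simulation than in the data. These steps used Python 3.11.15 and NumPy 2.4.6, and figures used Matplotlib 3.10.9.

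Alternatives fixed before the data were examined varied the pseudocount, the filter, the scaling of the libraries, limma's prior variance, a replicate block, the thresholds, the list test, and left out each library in turn. A fit with estimated depth as a covariate and a fit of the 4 siCasp8 libraries against the 2 deepest Scr libraries were added after the depths had been seen, and the list tests without Casp8 after the list results.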

Results

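The experiment asked which secreted genes change when Casp8, the gene of the initiator protease of death receptor signalling, is silenced in mouse hepatocytes. Poly-A RNA was measured in 4 Scr and 4 siCasp8 cultures of AML12, a hepatocyte line from the liver of a mouse that carried a human TGF-alpha transgene. Values are normalized per gene as deposited. Estimated depth was 31.6, 30.7, 38.4 and 51.8 M reads in Scr replicates 1 to 4 and 50.3, 56.8, 52.1 and 56.8 M reads in siCasp8 replicates 1 to 4. The Scr mean of 38.1 ± 9.77 M reads and the siCasp8 mean of 54.0 ± 3.31 M reads (SD, n = 4 each) gave p = 0.0571 in an exact two-sided permutation test. Values above 0 were present for 17718 to 18565 genes in the Scr libraries and for 18706 to 18947 in the siCasp8 libraries.

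Casp8 was lower in all 4 siCasp8 libraries than in any Scr library. Its value was 3972 ± 129 in Scr and 1480 ± 108 in siCasp8 (SD, n = 4 each), so 37.3% of the Scr level was left. The log2 fold change was -1.43 (SE 0.0525, limma adjusted p = 5.94e-09), and 2 of the 70 arrangements of the libraries gave a difference as large (exact p = 0.0286). Casp8 lies on chromosome 1 from 58795374 to 58847503 on the plus strand (GRCm38). Among 22 other genes of the caspase-8 and cell death machinery, 4 were higher and 7 lower, and the list without Casp8 was called neither by camera, which compares a list with the other genes (adjusted p = 0.845), nor by fry, which tests a list on its own (adjusted p = 0.546). With Casp8 in the list, 4 were higher and 8 lower, and after upper quartile rescaling 9 were higher and 5 lower. The death receptor gene Fas rose from 818 ± 43.6 to 1404 ± 78.6 (log2 fold change 0.78), and the caspase gene Casp9 rose from 1610 ± 115 to 2170 ± 130 (0.43). The deubiquitinase gene Cyld fell from 4253 ± 135 to 3333 ± 182 (-0.35).

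**Figure D1:**
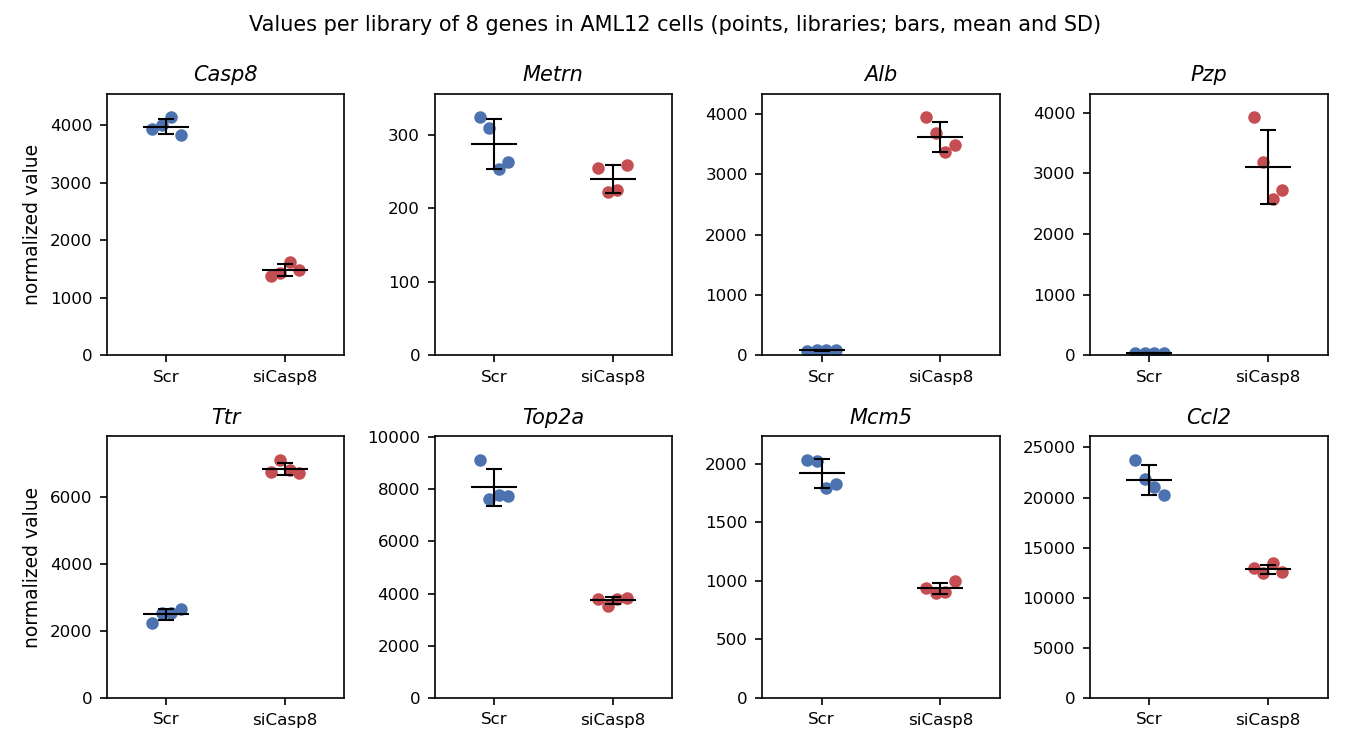
Normalized values (vertical axes, starting at 0) of 8 genes in the 4 Scr and 4 siCasp8 libraries, with points for libraries and bars for mean and SD. The siCasp8 libraries lay below all Scr libraries for Casp8, Top2a, Mcm5 and Ccl2, above them for Alb, Pzp and Ttr, and overlapped them for Metrn.

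After Casp8 silencing 15 of 25 tested hepatocyte identity genes were higher and 2 lower, and all 51 tested members of the lists for mitosis and for DNA replication were lower. These list calls were lost with an estimated correlation between genes (adjusted p = 0.141 for each). They were kept by fry (adjusted p = 4.88e-06 for hepatocyte identity and 1.36e-05 for each cell cycle list). The serum albumin gene Alb went from 86.4 ± 10.7 to 3626 ± 249 (SD, n = 4 each, log2 fold change 5.38), and Pzp, which encodes a serum protease inhibitor, went from 39.4 ± 5.15 to 3101 ± 607 (6.25). Across the transcriptome, 5689 of 14154 tested genes were called by limma, 2739 higher and 2950 lower in siCasp8, of which 264 rose and 148 fell by at least 1 on the log2 scale. With the libraries rescaled to a common upper quartile, which moved the median of all genes by 0.10, the split was 4475 higher and 1665 lower. That quartile was taken over values above 0, of which each siCasp8 library had more than any Scr library. This rescaling is therefore not independent of how many genes were detected in each group. With estimated depth as a covariate, a fit added after the depths had been seen, 2794 genes were called. The groups did not overlap for 37.5% of tested genes, where chance gives 2.86%.

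The other large rises were in G6pc, a member of the hepatocyte identity list, and in genes outside that list. G6pc, which encodes the glucose-6-phosphatase that releases glucose, went from 3.88 ± 2.45 to 122 ± 17.0 (log2 fold change 4.78). The complement gene C1s1 went from 299 ± 44.5 to 1712 ± 115 (2.52). Serpina10, which encodes a plasma inhibitor of coagulation proteases, went from 43.7 ± 9.73 to 237 ± 21.5 (2.44). The ribonuclease gene Rnase4 rose by 3.19, the carboxylesterase gene Ces2e by 2.88, the sphingolipid synthesis gene Sptssb by 2.88 and the GABA receptor subunit gene Gabrp by 2.32. All 7 of these genes were higher in 4 of 4 siCasp8 libraries, with limma adjusted p of at most 6.72e-05. Alb lies on chromosome 5 from 90460897 to 90476602 and Pzp on chromosome 6 from 128483567 to 128526720.

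The largest falls included genes of transport, matrix and cell division. Ranbp3l fell from 178 ± 69.0 to 26.9 ± 5.06 (log2 fold change -2.62). The chemokine gene Ppbp fell from 343 ± 32.0 to 91.3 ± 8.66 (-1.90), and the phosphate transporter gene Slc17a1 from 191 ± 22.6 to 55.5 ± 7.22 (-1.77). The transcription factor genes Mxd3 and Pax8 fell by 1.71 and 1.66, the ion transport genes Clca3b and Fxyd2 by 1.70 and 1.66, the organic anion transporter gene Slco4a1 by 1.58 and the kinetochore gene Spc24 by 1.54. Loxl2, which encodes an enzyme that crosslinks collagen, had the highest level of the 10 and fell from 4028 ± 160 to 1411 ± 147 (-1.52). All 10 were lower in 4 of 4 siCasp8 libraries, with limma adjusted p of at most 1.12e-05. Of the 57 genes besides Casp8 under the naming rule that fell and could be searched, 6 or 10.5% (among them Loxl2, Cyld, Sqle, Ambp and Zmat3) carried in their 3′ UTR the 7-base word GTCACTT, as did 2 of the 50 that rose (Vcam1 and Igf1) and 11.98% of all tested genes that could be searched. The word also occurs once in each of the 4 annotated Casp8 transcripts.

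Cell division genes fell as whole lists. All 26 tested genes of G2/M and mitosis were lower, with a median log2 fold change of -1.10 and a range of -1.21 to -0.56 (camera adjusted p = 2.13e-18, and adjusted p = 0.141 with an estimated correlation). Top2a, which encodes the topoisomerase that untangles chromosomes, fell from 8068 ± 709 to 3736 ± 145 (-1.11), and the spindle gene Tpx2 fell from 2330 ± 151 to 1045 ± 33.0 (-1.15). All 25 genes of DNA replication and S phase were lower too, with a median of -0.68 (camera adjusted p = 7.12e-15, and adjusted p = 0.141 with an estimated correlation). The helicase genes Mcm5 and Mcm4 fell from 1918 ± 126 to 935 ± 44.1 (-1.04) and from 2866 ± 206 to 1560 ± 56.4 (-0.87). Of 9 tested replication-dependent histone genes, 2 were called, H2bc4 and H1f2, each higher by 0.15. Neither was called when adjusted over the list alone or with the depth covariate. The list was not called by camera (adjusted p = 0.242) but was by fry (adjusted p = 0.0124). The largest log2 fold change among its members, 2.50, was not called. Since the libraries hold poly-A RNA, histone transcripts without a poly-A tail would largely be missed.

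Of 34 hepatocyte identity genes 25 were tested, and the others had a mean value under 10. Of the 25 tested, 15 were higher and 2 lower, with a median log2 fold change of 0.50 (camera adjusted p = 1.55e-05, and adjusted p = 0.141 with an estimated correlation). Ttr, which encodes the thyroid hormone carrier transthyretin, rose from 2495 ± 176 to 6852 ± 178 (1.46). The 2 genes that fell were Ambp, from 10117 ± 559 to 7785 ± 399 (-0.38), and Apob, which encodes the main protein of very low density lipoprotein, from 26046 ± 1567 to 21951 ± 1579 (-0.25). Genes of fatty acid oxidation and PPARA targets rose as a list, with 13 of 23 higher, 1 lower and a median of 0.20 (camera adjusted p = 0.00016, and adjusted p = 0.141 with an estimated correlation). Vnn1 rose from 861 ± 39.9 to 1836 ± 67.7 (1.09), and Cpt1a, the gene of the enzyme that admits fatty acids to mitochondria, rose from 14004 ± 254 to 18312 ± 173 (0.39). The lipid droplet gene Plin2 fell by 0.21, a call lost with the depth covariate.

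Genes of cholesterol biosynthesis and uptake fell. Of 24 members, 17 were lower and 1 higher, with a median log2 fold change of -0.32 (camera adjusted p = 1.55e-05, and adjusted p = 0.141 with an estimated correlation), and 2 were higher when adjusted over the list alone. Sqle, which encodes an early sterol enzyme, fell from 4064 ± 50.1 to 2646 ± 88.7 (-0.62). Mvd was the member that rose (0.33). Genes of fatty acid and triglyceride synthesis went both ways, with 6 of 19 higher and 7 lower, or 7 and 4 after upper quartile rescaling (camera adjusted p = 0.614). The triglyceride synthesis gene Dgat2 and the desaturase gene Scd1 rose by 0.74 and 0.54, while the elongase gene Elovl6 and the desaturase gene Fads1 fell by 0.56 and 0.43.

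Secreted signalling factors, the class that the series' title names, changed in both directions. Of 116 tested members, 36 were higher, 38 were lower and 42 were not called (37 and 39 when adjusted over the list alone, 43 and 34 after upper quartile rescaling), and the list was not called by camera (adjusted p = 0.818) but was by fry (adjusted p = 0.0329). Hgfac, which encodes the protease that activates hepatocyte growth factor, rose from 915 ± 52.9 to 1943 ± 60.8 (log2 fold change 1.09). The growth factor genes Igf1 and Vegfa rose from 210 ± 7.46 to 398 ± 48.5 (0.91) and from 1897 ± 137 to 2761 ± 70.6 (0.54). The chemokine genes Cxcl16 and Ccl20 rose by 0.64 and 0.39, and the galectin gene Lgals3 by 0.57. Among those that fell, the monocyte chemoattractant gene Ccl2 went from 21741 ± 1496 to 12836 ± 439 (-0.76), and Ccn4, which encodes a matrix-associated signalling protein, went from 11657 ± 296 to 6585 ± 172 (-0.82). The growth factor genes Pdgfb and Tgfb3 went from 4954 ± 222 to 3006 ± 144 (-0.72) and from 4543 ± 189 to 2743 ± 171 (-0.73). The binding protein gene Igfbp7 fell by 0.70 and the semaphorin gene Sema3e by 0.56. These 12 genes were each on one side in 4 of 4 siCasp8 libraries, with limma adjusted p of at most 1.38e-05.

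Metrn, which encodes the secreted neurotrophic factor meteorin, was 288 ± 34.1 in Scr and 240 ± 19.2 in siCasp8 (SD, n = 4 each). Its log2 fold change was -0.25 (SE 0.103, 95% interval -0.48 to -0.03), and limma's adjusted p was 0.0676, so it was not called. The gene passed without Scr replicate 3 (adjusted p = 0.0345, the lowest over the alternatives) and under quantile normalization (adjusted p = 0.0499), and with the depth covariate its log2 fold change was -0.06 (adjusted p = 0.839, the highest). It lies on chromosome 17 from 25793221 to 25797136 on the minus strand, where another annotated protein-coding gene overlaps it on the same strand.

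Matrix genes and targets of the growth regulator YAP were lower in part. Of 20 YAP/TEAD targets, 14 were lower and 3 higher, with a median log2 fold change of -0.30 (camera adjusted p = 0.000783, and adjusted p = 0.485 with an estimated correlation). Ccn1, which encodes a matrix-associated signalling protein, and the muscle repeat gene Ankrd1 fell by 0.87 and 0.52, while Fjx1 and Ccn2 rose by 0.72 and 0.27. Of 31 matrix and remodelling genes, 14 were lower and 5 higher (15 and 7 when adjusted over the list alone, 8 and 7 after upper quartile rescaling). The list was not called by camera (adjusted p = 0.0909, and adjusted p = 0.0377 without siCasp8 replicate 4) but was by fry (adjusted p = 0.00466). Sparc fell by 0.51, while the laminin gene Lamb3 and the collagen gene Col4a5 rose by 0.43 and 0.35. Of 16 TGF-beta response genes, 5 were lower, among them Itgb6 (-0.65) and Ski (-0.41), and 2 were higher, Bhlhe40 (0.47) and Cdkn2b (0.24), with a camera adjusted p of 0.507 and 4 lower and 4 higher after upper quartile rescaling.

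Inflammatory and stress lists were not called by camera, and fry called those of interferon-stimulated genes and of folding genes (adjusted p = 0.0329 for each). Of 23 interferon-stimulated genes, 9 were higher, such as Cxcl10 (log2 fold change 0.76) and Gbp2 (0.60), and 3 lower, such as Ifit3 (-0.97) and Ifit2 (-0.55), with a camera adjusted p of 0.158 and 10 higher when adjusted over the list alone. Of 22 NF-kB and inflammatory targets, 5 were higher, led by the adhesion gene Vcam1, which rose from 5084 ± 185 to 9434 ± 432 (0.89), and 6 were lower, such as the neutrophil chemokine gene Cxcl5 (-0.82), with a camera adjusted p of 0.704. Of 24 p53 targets, 5 were higher, such as Ephx1 (0.80), and 10 lower, such as Zmat3 (-0.62) and Gdf15 (-0.83), with a camera adjusted p of 0.454 and 6 higher when adjusted over the list alone. Of 25 integrated stress response genes, 8 were lower, such as the serine synthesis genes Psat1 (-0.68) and Phgdh (-0.40), and 5 higher, such as Sesn2 (0.33) and Trib3 (0.73), with a camera adjusted p of 0.643. Of those, Phgdh and Trib3 were not called with the depth covariate. Of 19 folding genes of the endoplasmic reticulum, 5 were higher, such as Xbp1 (0.25) and Sel1l (0.16), and 1, Hyou1 (-0.35), was lower, with a camera adjusted p of 0.454. After upper quartile rescaling the higher and lower counts were 7 and 5 for NF-kB targets, 7 and 6 for p53 targets, 8 and 6 for the integrated stress response and 11 and 1 for folding genes.

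Of 22 NRF2 targets, 7 were higher and 6 lower, or 10 and 3 after upper quartile rescaling (camera adjusted p = 0.845). The glutathione synthesis gene Gclc rose from 17454 ± 256 to 27706 ± 1536 (log2 fold change 0.67) and the transferase gene Gsta4 by 0.38, while the glutathione reductase gene Gsr fell from 17514 ± 1367 to 7738 ± 611 (-1.18) and Me1 fell by 0.39. Of 21 genes of the ERK and immediate early response, 7 were higher, such as Etv5 (1.06) and Egr1 (0.72), and 3 were lower, such as the phosphatase gene Dusp1 (-1.27) and Ier3 (-0.44), with a camera adjusted p of 0.507, a fry adjusted p of 0.0329 and 4 lower when adjusted over the list alone. Of 22 hypoxia and glycolysis genes, 9 were lower, such as the enzyme genes Eno1 (-0.37) and Gapdh (-0.34), and 5 higher, such as the hexokinase gene Hk1 (0.27), with a camera adjusted p of 0.242, a fry adjusted p of 0.0189, 11 lower when adjusted over the list alone, and 6 lower and 6 higher after upper quartile rescaling. Autophagy and lysosome genes rose as a list by a median of 0.12, with 14 of 25 higher and 2 lower, or 3 lower when adjusted over the list alone (camera adjusted p = 0.0206, adjusted p = 0.489 with an estimated correlation, and adjusted p = 0.0551 without Scr replicate 3). Gabarapl1 rose by 0.54 and the lysosomal enzyme gene Hexa by 0.41, while Wipi1 and Map1lc3a fell by 0.12 and 0.15, calls that were lost with the depth covariate. Cytosolic ribosomal protein genes rose by a median of 0.08, with 14 of 43 higher and 3 lower, or 31 and 1 after upper quartile rescaling and 24 and 1 under quantile normalization (camera adjusted p = 0.0437, and adjusted p = 0.668 with an estimated correlation). That call was lost without Scr replicate 3 (adjusted p = 0.134), Scr replicate 4 (0.0921), siCasp8 replicate 1 (0.0659) or siCasp8 replicate 3 (0.087). Rpl32 rose by 0.19 and Rpl5 fell by 0.47. Of 13 mitochondrially encoded genes, 1 was called, mt-Nd6 (0.36), and none when adjusted over the list alone (camera adjusted p = 0.614).

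**Figure D2:**
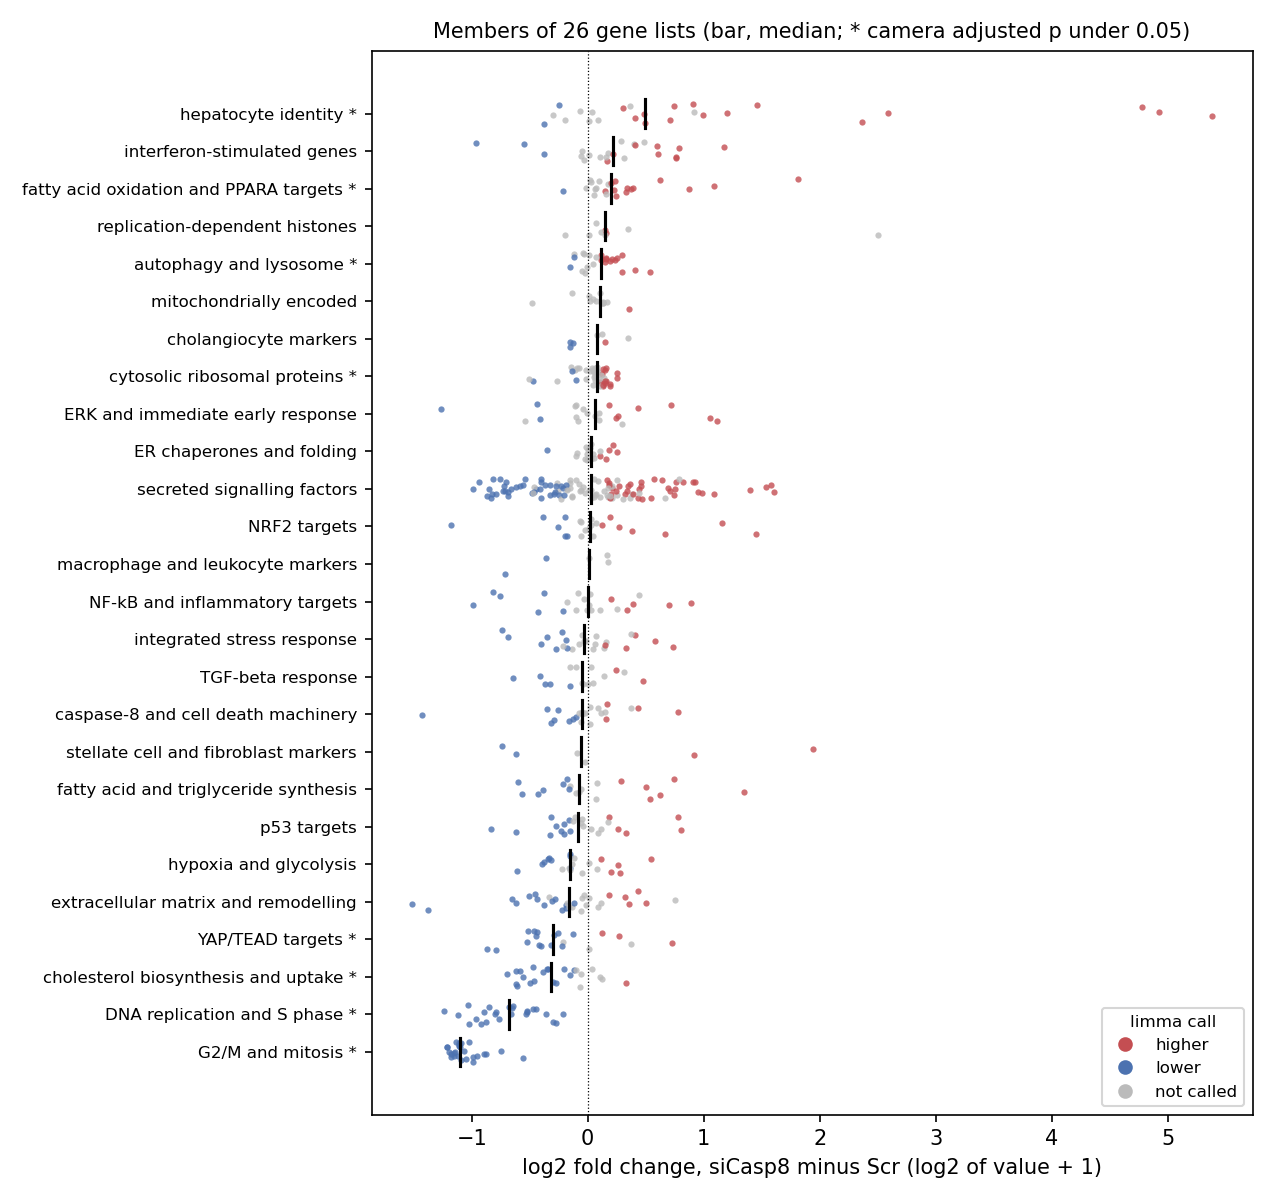
Log2 fold changes (horizontal axis) of the tested members of 26 gene lists, with points coloured by limma call, black bars for list medians and asterisks for lists with a camera adjusted p under 0.05. All points of G2/M and mitosis lay between -1.21 and -0.56, and Alb, at 5.38, was the farthest point to the right.

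Markers of other cell types did not rise together. Of 12 cholangiocyte markers 7 were tested, with 1 higher, Sox9 (log2 fold change 0.15), and 3 lower, such as Krt19 (-0.15), or 2 higher and 3 lower when adjusted over the list alone and 2 higher and none lower under each of 3 rescalings (camera adjusted p = 0.845). Krt19 was at 7764 ± 419 in Scr and 6975 ± 323 in siCasp8, and its call was lost with the depth covariate. Of 14 stellate cell and fibroblast markers 6 were tested, with 2 higher, Des and Pdgfra, and 2 lower, Tagln and Col1a1 (camera adjusted p = 0.845), all of them calls that the depth covariate ended. Thy1, the most abundant of these markers, was at 271 ± 17.4 and 269 ± 35.3. Of 14 macrophage and leukocyte markers 5 were tested and 2 were lower, Cd14 from 2149 ± 99.5 to 1675 ± 54.5 (-0.36) and Csf1r from 569 ± 30.1 to 347 ± 29.4 (-0.72), with a camera adjusted p of 0.469 and a fry adjusted p of 0.000859. Of 13 endothelial markers 4 were tested, too few for a list test, and none was called, or 1 higher after upper quartile rescaling. Pecam1 was at 304 ± 161 in Scr and 224 ± 53.1 in siCasp8, and Flt1 was at 100.1 ± 10.8 and 132 ± 30.6.

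The libraries separated by group along the first principal component, which held 43.1% of the variance. Pearson's r of log2 values across genes, which are not independent replicates, was at least 0.987 between Scr libraries, at least 0.992 between siCasp8 libraries and from 0.979 to 0.986 between groups. Mitochondrially encoded genes held 4.88 ± 0.827% of the Scr values and 5.19 ± 0.385% of the siCasp8 values (SD, n = 4 each, exact two-sided permutation p = 0.543).

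**Figure D3:**
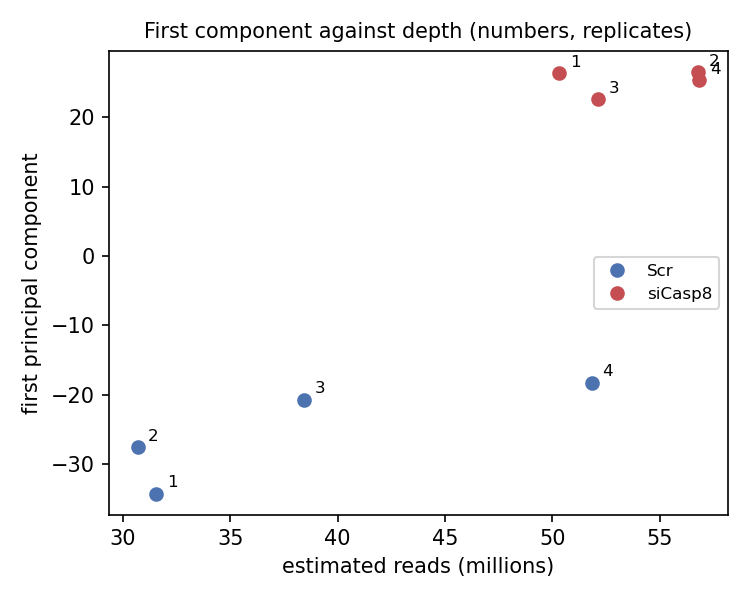
The first principal component of the log2 values (vertical axis) against estimated depth in M reads (horizontal axis), with 1 point per library. Scr replicate 4, at 51.8 M reads, lay on the Scr side at -18.2. The siCasp8 libraries of like depth, replicates 1 and 3 at 50.3 and 52.1 M reads, lay at 26.3 and 22.6. The shallower Scr replicates 1 to 3, at 31.6, 30.7 and 38.4 M reads, lay farther from siCasp8, at -34.2, -27.6 and -20.7.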

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

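Of 240 sets of 4 libraries (115 genes under the naming rule and 5 library measures in each group), 10 had a library far from the other 3, where chance gives about 12. All 10 concern genes, and no library measure stood apart. In the Scr group, replicate 1 had the highest values of Top2a (9126, others 7625 to 7790), Psat1 (12903, others 10990 to 11179) and Hgfac (993.7, others 877 to 896), and replicate 3 had the lowest value of Pzp (31.8, others 41.4 to 42.9). In the siCasp8 group, replicate 1 had the highest values of Apob (24314, others 21035 to 21305) and Lgals3 (5301, others 4598 to 4657), replicate 2 had the lowest value of Top2a (3521, others 3788 to 3834), replicate 3 had the highest value of Cyld (3603, others 3211 to 3278), and replicate 4 had the highest value of Ier3 (4144, others 3812 to 3840) and the lowest of Vcam1 (8789, others 9614 to 9701). These 9 genes were called with any 1 library left out.

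The line of the table without a gene symbol, which entered no comparison, was higher in siCasp8. Its mean was 26351 ± 1581 in siCasp8 and 23276 ± 1058 in Scr (SD, n = 4 each), a ratio of 1.13, and all 4 siCasp8 values lay above the highest Scr value of 24488 (exact two-sided permutation p = 0.0286, the smallest that 4 against 4 can give).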

How the results depend on the processing

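Depth as a covariate and the fit against the 2 deepest Scr libraries were chosen after the depths had been seen, the list tests without Casp8 after the list results, and all other settings before. Casp8 was lower and called in every setting, with log2 fold changes from -1.47 to -1.33. The count of called genes lay between 4799 and 5743 with 1 library left out. It was 412 (264 higher, 148 lower) with a log2 fold change of at least 1, 2794 (1303 higher, 1491 lower) with the depth covariate and 4935 with the 4 siCasp8 libraries against Scr replicates 3 and 4. At an adjusted p under 0.01 it was 3900 (1821 higher, 2079 lower). The upper quartile was taken over values above 0, and rescaling to it moved the median log2 fold change of all genes to 0.10 and gave 4475 higher and 1665 lower, or 72.9% higher against 48.1% as deposited. The cause was not tested for the depth covariate, which differs between the groups. In no setting was a gene called in the other direction. Of the 8 lists called with the preset correlation, 0 were called with an estimated one. Fry, which tests each list on its own, called 17. Among them were those 8 lists and the cell death list, which it did not call without Casp8. The matrix list passed with no filter, with a mean of at least 50, after upper quartile rescaling and without siCasp8 replicate 4, and the ribosomal protein list was lost with no filter (adjusted p = 0.0523). Of the 114 genes besides Casp8 under the naming rule, 19 changed side under some setting other than a stricter threshold, and 0 reversed. With 1 library left out, the calls of Map1lc3a and Col1a1 ended for 7 of the 8 libraries (highest adjusted p 0.112 and 0.114), of mt-Nd6 for 6 (0.121), of Tagln for 5 (0.108), of H2bc4 and H1f2 for 4 (0.0902 and 0.0844), of Wipi1 for 3 (0.0614), of Pdgfra for 2, siCasp8 replicates 1 and 4 (0.0786), and of Krt19 for siCasp8 replicate 3 (0.0538). Flt1 was called without siCasp8 replicate 3 (0.0201). For the lists of NF-kB targets, fatty acid synthesis, secreted factors, and macrophage and stellate markers, none of them called by camera, the median or the mean had another sign than the test. The replicate block gave 6020 calls and changed no list. Same-numbered libraries deviated together by r = 0.08, 0.04, 0.17 and 0.06, so the numbers were not taken as pairs, although each of the 8 libraries correlated best with its own number, a hint from the data only. Count models on whole reads (the edgeR and DESeq2 alternatives) were not run, since the values did not give whole reads for nearly all genes. Depth limits the low genes most: 1 read was worth 0.776 to 1.47, and G6pc in Scr lay at a few reads.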

Other observations

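The grouping by symbol, the fits with depth and the rescaling test for the cell cycle lists were chosen after the results they bear on had been seen. Genes were grouped by the letters that open their symbols, which gave 241 groups of at least 8 tested genes, and each group was tested with camera. With the preset correlation 14 groups passed, and none did with an estimated correlation, where the smallest adjusted p was 0.438. The members named here were chosen after their values had been seen. The strongest was that of cytochrome P450 genes, the enzymes that oxidise drugs, steroids and fatty acids, with 30 of 49 higher, 4 lower and a median log2 fold change of 0.60 (camera adjusted p = 1.64e-07). Cyp2c68 rose from 1446 ± 106 to 4215 ± 182 (1.54), Cyp3a13 from 1971 ± 159 to 4720 ± 286 (1.26) and Cyp1a1 from 537 ± 15.4 to 1137 ± 15.0 (1.08). Of 11 glucuronosyltransferase genes, 10 were higher, with a median of 1.19 (adjusted p = 0.000116). Ugt2b34 rose from 1910 ± 247 to 5083 ± 138 (1.42), while Ugt1a6a, Ugt1a6b and Ugt1a9 share exons and their values are not independent. Lipid transporters of the Abca group were higher in 8 of 12 genes and lower in 1, Abca2 (-0.18, a call lost under all 3 rescalings), with Abca6 from 391 ± 6.83 to 1293 ± 102 (1.72) and Abca8b from 2438 ± 167 to 4986 ± 136 (1.03) (adjusted p = 0.0119). Guanylate-binding protein genes, known as interferon-induced GTPases, were higher in 6 of 9, led by Gbp7 (1.14) (adjusted p = 0.0119).

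Some groups of basic cell machinery were lower by small amounts. Of 14 Psmd genes of the proteasome's regulatory particle, 9 were lower and none higher, with a median log2 fold change of -0.14 (camera adjusted p = 0.00678), such as Psmd11 from 5423 ± 92.9 to 4411 ± 153 (-0.30). Of 20 nucleoporin genes, 10 were lower, with a median of -0.17 (adjusted p = 0.00705), led by Nup93 from 1918 ± 125 to 1208 ± 55.7 (-0.67). Of 13 Lsm genes of RNA processing, 8 were lower, with a median of -0.23 (adjusted p = 0.00719). None of the 3 passed with an estimated correlation (adjusted p = 0.642, 0.438 and 0.642). The medians of these groups kept their sign under the 3 other scalings, but after upper quartile rescaling, which moved all genes up by 0.10, only 3 Psmd, 6 Nup and 5 Lsm genes were called lower and 1 Nup gene was called higher.

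The real grouping called 5689 genes, and the highest count among the other 34 of the 35 splits of the 8 libraries into 4 and 4 was 1. Only 1 split, the real one, reached its count, which argues against chance assignment of the libraries. It cannot exclude chance, since 1 in 35 is the smallest share that these splits can give. The other splits mix both groups, so a difference between the groups widens their spread and lowers their counts.

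Genes with certain 7-base words in the 3′ UTR were lower on average than genes without them. The strongest word was GTCACTT, present in 1346 of 11293 genes, with a shift of -0.098 on the log2 scale and t = -10.35, while the strongest fall in 100 shuffles had t = -4.82. Leaving out the cell cycle lists gave t = -10.1. Of the 5 words that passed the shuffles, AGTCACT and TCAGTCA overlap GTCACTT in Casp8, and TATTTAT and TATTTTT are rich in A and T. Of tested genes with the word, 35.7% were lower and 13.6% higher, against 19.9% and 21% of those without, and 46.7% of 195 genes with at least 2 copies were lower. Unlike the regression, these shares were not adjusted for UTR length or base composition.

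The word lies in the coding sequence of all 4 Casp8 transcripts, at chromosome 1, 58844810 to 58844816, on the plus strand (GRCm38), and 15.6% of tested words occur in a Casp8 transcript. With t = -10.35 for the fall, this is consistent with the hypothesis that a Casp8 siRNA with this seed match lowered other transcripts too. No word rose beyond the shuffles (t = 4.40 for ATCTTCT against 4.88), which argues against a strong seed effect of the scrambled siRNA. A regulator of the cells themselves that uses the same word was not tested and stays open, and the siRNA sequences were not given in the sources used here.

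The rise of hepatocyte transcripts was set against RNA from liver tissue, which would bring its abundant transcripts along with Alb. Of 30 such transcripts, 14 had a mean of at least 10 in these cells and 16 did not, with Fabp1, Apoa2 and Ahsg, named after their values had been seen, at or near 0 in both groups, and 11 were called higher and 1 lower. The rise was at least 1% of that of Alb for 9 of the 30, but the median rise of the 30 was 0.0681% of it, which argues against tissue RNA. With depth as a covariate, entered here as the log2 of log2 depth, the 15 genes called higher kept 107% of their median fold change. In that fit 14 stayed called, and the depth fits of the sections above used the log2 depth. Against the 2 deepest Scr libraries the median log2 fold change of the 15 genes was 1.04, and 15 stayed called. Both fits argue against depth as the sole cause, although the 15 genes had been chosen as called higher in these same libraries. Neither fit fully separates depth from group. Depth differs between the groups, and Scr replicate 3, at 38.4 M reads, lay below every siCasp8 library (50.3 M or more). The word of the strongest rise did not pass the shuffles, so the 95.5% of the median that members without it kept decides nothing, and a seed match of the scrambled siRNA in these transcripts stays open, as does an effect of Casp8 silencing or of other transcripts lowered by its siRNAs.

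For the fall of the 51 cell cycle genes, the median log2 fold change was -0.96. With depth as a covariate, again as the log2 of log2 depth, it was -0.88, or 91.1% of its size. In that fit 49 genes were still called. Under the 3 rescalings at least 89.6% of the median was left, so these scalings do not account for the fall. They moved the median of all genes to at most 0.10, too little to remove a median of -0.96. Other faults of normalization were not tested. The 42 members without GTCACTT in the 3′ UTR kept 101% of the median and 42 of them were lower. This word in the annotated 3′ UTRs of the members therefore does not account for the fall. Matches to other words, or in the coding sequences of the members, were not tested. An effect of the loss of Casp8 and an effect of other transcripts targeted through the seed both stay open, since no library here separates them. Other causes were not tested, and cell division itself was not measured.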
